A study of Homo sapiens with 16 samples.

How the data were processed

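Gene expression was measured by RNA sequencing in IMR32 cells, a human neuroblastoma line, after 24 h in DMSO (the vehicle), 1.25 µM indisulam, 4 µM alectinib or both drugs together. Each of the 4 treatments had 4 libraries, 16 in all, and every library was assigned to its group from its GEO title. Per the labels' protocols, total RNA was purified with RNeasy columns, and polyadenylated RNA was made into libraries with the NEBNext Ultra II RNA kit and sequenced as paired 150 bp reads on a NovaSeq 6000. The labels number the libraries of a group but do not say that they came from separate cultures. The p-values given here therefore measure only the spread between these libraries, which may be partly technical.

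The authors deposited 1 table of raw counts per gene, which holds whole numbers, has not been normalised and has 1 column for each library. Per the submitters' processing notes, the build was GRCh38 and the tools were FastQC 0.11.9, Trimmomatic 0.39, HISAT2 2.2.1 and featureCounts 2.0.1. Their settings are not given in the sources used here, including whether strand was used, how reads that map to several places were treated, and whether reads or read pairs were counted. Counts of near-identical paralogs (such as HSPA1A and HSPA1B, the replication-dependent histones, and ribosomal protein genes with their pseudogenes) and of genes whose exons overlap another gene are therefore uncertain. The deposited table also holds other columns, the start, end and exonic length of each gene in bases, and the coordinates printed here are those. The starts, ends and strands of all 58735 genes were equal to those of GENCODE 29, which was the source of exon, transcript and neighbour information. A set of 27 gene names had been turned into dates in the deposited table, and these names were restored from the gene identifiers.

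Depth was between 55.1 and 63.7 M counts (M, 1e6) in 15 libraries and 90.2 M in alectinib replicate 1. Of the 58735 genes, 17873 had no count in any library. The default expression filter of edgeR 4.0.16 (filterByExpr by group) left 22433 genes, and the genes it left out held at most 0.0654% of the counts of any library. Counts were scaled by TMM and fitted with the quasi-likelihood model of edgeR in R 4.3.3, with 1 mean for each treatment over all 16 libraries and 12 residual degrees of freedom. Each drug treatment was compared with DMSO, and the combination with each single drug. The interaction was the combination minus indisulam minus alectinib plus DMSO on the log2 scale, that is, the deviation of the combination from the sum of the single-drug changes. P-values were adjusted over the 22433 genes by the Benjamini-Hochberg method, a gene was called changed at an adjusted p under 0.05, and all tests were two-sided. Log2 fold changes are given ± their standard error (SE), obtained from the fold change and the F statistic. The fold changes of edgeR use a prior count of 0.125, which draws the changes of genes with few counts towards 0. Levels are counts scaled to a library total of 1e6 (CPM) with TMM scaling, as mean ± SD over the 4 libraries of a group.

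A collection of 33 gene lists (drug targets, splicing, stress responses, cell cycle, metabolism, neuroblastoma identity and markers of other cell types) was fixed before the data were examined, as were the tests, the comparisons and the rule for naming genes. Of the 958 distinct genes in the lists, 956 were found in the table. The 31 lists with at least 5 tested members were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and the preset inter-gene correlation of 0.01, with p-values adjusted over the 31 lists of a comparison. The marker lists for epithelial and blood cells had fewer tested members and were not tested. The same test with a correlation estimated from the data, and fry, were run beside it. For each list, the count of changed members is given with p-values adjusted over all 22433 genes and, separately, adjusted over the list alone.

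The genes named in the text were taken by rule. For each treatment against DMSO, these were the 8 protein-coding genes with the largest positive and the 8 with the largest negative log2 fold change among genes that were called changed, had a mean of at least 5 CPM and had no overlap between the CPM values of the 2 groups. The combination against each single drug gave 4 and 4 genes by the same rule, and the interaction gave 6 and 6 without the condition on overlap. All members of the list of drug targets and adaptors were named as well, and examples from the other lists were taken from their first 4 members in order of p, with none for some lists. MYCN in indisulam and CDKN1A were named outside these rules.

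The overlap of the indisulam and alectinib changes was set beside 20 simulations in which neither drug changed any gene but the DMSO libraries were shared, beside the overlap of independent lists, and beside splits of the DMSO libraries into 2 for each drug. The relation of the combination to the sum of the single drugs was described by a slope through the origin over genes called changed in any treatment against DMSO. Protein-coding genes in the longest and the shortest 20% of genomic span, and those with a single exon, were tested as sets with camera.

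The gene and list tests were tested on simulated data with 200 genes changed by 1.5-fold, 2-fold or 4-fold. For indisulam against DMSO (20987 simulated genes tested), the changed genes were recovered in 46.0%, 65.1% and 93.9% of cases for the 3 sizes, and 4.35% of the calls were genes that had not been changed. For the interaction (21002 genes) the recovered shares were 31.7%, 51.6% and 80.3%, and 3.64% of the calls were unchanged genes. The share of unchanged genes among the calls was 3.03% for alectinib against DMSO, 5.19% for the combination against DMSO, 8.39% for the combination against indisulam and 5.88% for the combination against alectinib. In a simulation of the combination against DMSO, the 1 list that had been changed was the 1 list called. Simulated genes varied independently of each other, so this cannot show whether the preset correlation suits the real data. The recovered and unchanged shares come from data with only 200 changed genes and no GC trend, so they may not hold for the real comparisons. When a GC trend alone was put into the simulated combination libraries, 8014 genes were called against DMSO, and 0 with the trend removed.

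The alternatives tried were DESeq2 size factors and upper-quartile factors in place of TMM, no low-count filter and a stricter one (at least 10 counts in 4 libraries and a mean of at least 5 CPM), the Wald test of DESeq2 1.42.0, limma-voom, fits on only the 2 groups compared, the replicate number as a block, a test against a log2 change of 0.5 (glmTreat), and leaving out each library in turn. Removal of each library's trend on GC content and transcript length was added after the data were seen. Isoforms, splice junctions and retained introns were not analysed here, because the table holds 1 count per gene. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.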

Results

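Transcripts were counted in 16 libraries of IMR32 cells, a human neuroblastoma line, arranged as a 2 by 2 layout of indisulam and alectinib. Indisulam is an aryl sulfonamide that brings the splicing factor RBM39 to the ubiquitin ligase adaptor DCAF15, after which RBM39 is degraded. Alectinib is an inhibitor of the receptor tyrosine kinase ALK, and the study's title describes it as acting on further targets and disturbing RNA splicing together with RBM39 degraders. Each of the groups DMSO, indisulam (1.25 µM), alectinib (4 µM) and combination had 4 libraries taken after 24 h. The totals were 56.7, 57.1, 57.9 and 58.8 M counts (M, 1e6) in DMSO replicates 1 to 4, and 63.4, 57.7, 60.7 and 63.7 M in the indisulam replicates. Alectinib replicates 1 to 4 had 90.2, 58.7, 58.4 and 60.7 M, and the combination replicates 55.1, 58.6, 61.1 and 57.8 M.

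The libraries separated by treatment, and on the first components no library lay among those of another group. Principal component 1 held 44.1% of the variance and component 2 held 15.9%. Mitochondrially encoded genes took 5.38% ± 0.26 (SD, n = 4) of the counts in DMSO, 6.48% ± 0.17 in indisulam, 5.63% ± 0.74 in alectinib and 6.61% ± 0.13 in the combination. Replicate pairs differed by more than counting noise, with chi-square values per degree of freedom between 9.03 and 36.2, which does not show whether the libraries came from separate cultures.

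**Figure D1:**
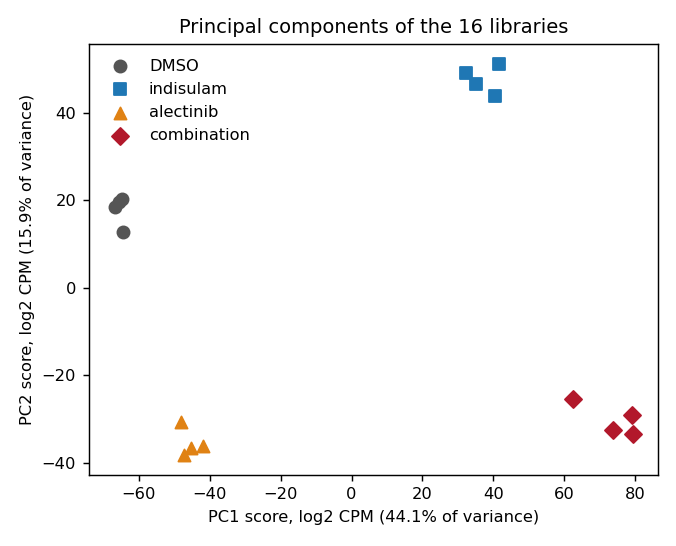
Scores of the 16 libraries on principal components 1 and 2 of log2 CPM, with 1 point for each library and 1 colour and marker for each treatment. Component 1 (44.1% of the variance) ran from DMSO and alectinib to indisulam and the combination, and on component 2 (15.9%) both groups that received alectinib lay below 0.

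The mRNAs of the drug targets were described first. RBM39 (ENSG00000131051, GRCh38 chromosome 20, 35701347 to 35742312, minus strand) rose in every treatment, from 271 ± 18.9 CPM (SD, n = 4) in DMSO to 532 ± 25.5 in indisulam, 364 ± 17.2 in alectinib and 734 ± 38.1 in the combination. These were log2 changes of 0.97 ± 0.06 (SE), 0.42 ± 0.06 and 1.44 ± 0.06, and the interaction was 0.04 ± 0.08 (adjusted p = 0.808). The protein, which indisulam acts on, was not measured here. ALK (ENSG00000171094, chromosome 2, 29192774 to 29921566, minus strand) fell from 245 ± 8.61 CPM in DMSO to 190 ± 14.1 in indisulam, 170 ± 14.8 in alectinib and 119 ± 8.52 in the combination, the last a log2 change of -1.05 ± 0.07. RBM23, the nearest relative of RBM39, rose with indisulam (0.62 ± 0.06) and the combination (0.73 ± 0.06) and was at -0.09 ± 0.06 in alectinib, which did not pass the test.

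Of the other targets and adaptors, DCAF15 was not called changed in any comparison, with log2 values between -0.04 and 0.04. DDB1, which links DCAF15 to the cullin ligase, fell in all 3 treatments (-0.30, -0.19 and -0.61 in indisulam, alectinib and combination), and its cofactor DDA1 rose in the combination (0.58 ± 0.08) beyond the sum of the single drugs (interaction 0.43 ± 0.11, adjusted p = 0.0133). CUL4A, the cullin, was at -0.01 in indisulam, which did not pass, and fell by 0.19 in alectinib and by 0.45 in the combination. SRPK1, a kinase of SR splicing proteins, fell with indisulam (-0.66 ± 0.07) and the combination (-0.74 ± 0.07) and was at -0.02 in alectinib. SRPK2 was not called in any comparison. SRPK3, at only 3.71 ± 1.51 CPM in DMSO, fell with alectinib (-1.50 ± 0.30) and the combination (-2.54 ± 0.33). Among the CLK kinases, which also phosphorylate SR proteins, CLK3 rose in indisulam, alectinib and the combination by 0.81, 0.41 and 1.23. CLK1 and CLK4 rose in indisulam (0.37 and 0.56) and the combination (0.65 and 0.85). CLK2 fell in both single-drug groups (-0.30 and -0.22) and was at 0.03 ± 0.07 in the combination, with an interaction of 0.56 ± 0.09 (adjusted p = 0.000393). RET was called only in the comparisons of the combination with DMSO (-0.78 ± 0.17), indisulam and alectinib, and LTK had 91 counts in total and was not tested. The alectinib calls of DDB1, CUL4A and CLK2 did not pass under upper-quartile scaling.

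**Figure D2:**
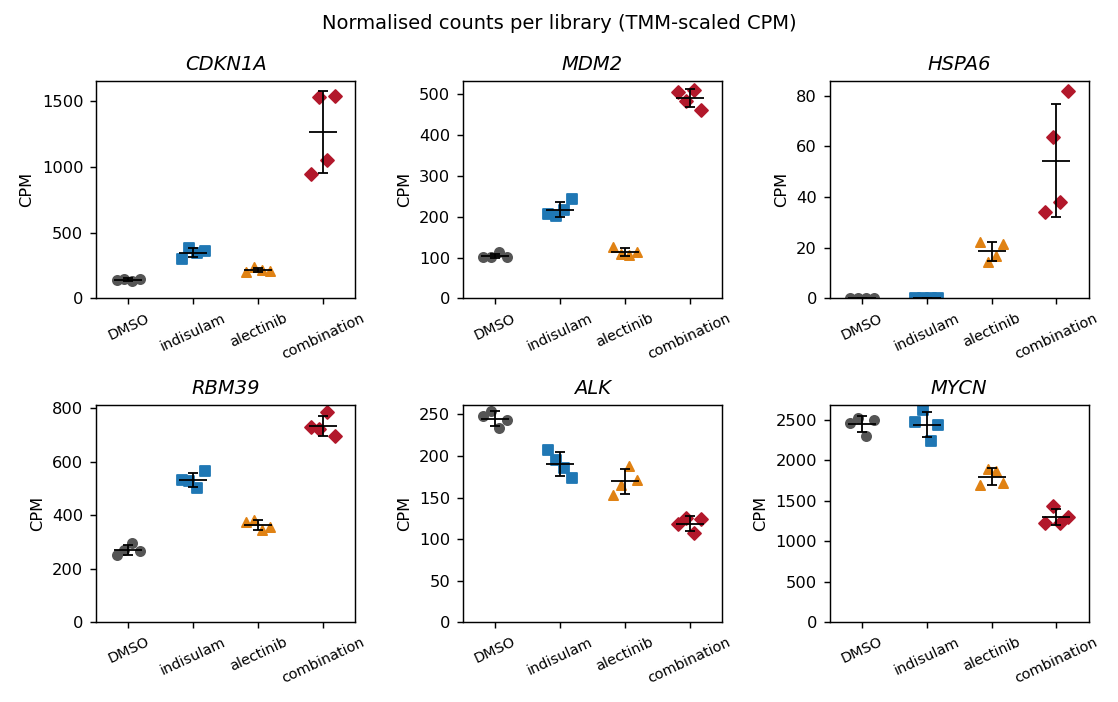
Normalised counts (CPM, TMM-scaled) of CDKN1A, MDM2, HSPA6, RBM39, ALK and MYCN, with 1 point for each library, the mean as a horizontal mark and the SD over 4 libraries as the error bar, on linear axes that start at 0. CDKN1A reached 1266 CPM and MDM2 490 CPM in the combination, while ALK was lowest there (119 CPM).

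Indisulam against DMSO asked what that drug alone did to the transcriptome. Genes of cholesterol, fatty acid and endoplasmic reticulum (ER) chaperone pathways and of DNA replication fell, and the lists of p53 targets, ribosomal proteins, SR factors and the core spliceosome rose. With an estimated correlation 0 of 31 lists were called. At an adjusted p under 0.05 in edgeR's quasi-likelihood test, 5165 genes were higher and 5569 lower, of which 1508 and 1528 changed at least 2-fold. Upper-quartile scaling gave 6339 higher and 4690 lower, so the balance of directions depended on the scaling. It also depended on the type of gene. Apart from mitochondrially encoded genes and those named for their fold change, 446 protein-coding genes were called at least 2-fold higher and 924 lower. DCAF4L1, an intronless relative of a DCAF adaptor, rose from 0.985 ± 0.229 to 21.7 ± 2.72 CPM (SD, n = 4), a log2 change of 4.46 ± 0.14 (SE). The oviductal glycoprotein OVGP1 (4.12 ± 0.15), the GTPase gene RAB44 (3.80 ± 0.26), the leukotriene hydroxylase CYP4F3 (3.23 ± 0.18), the ubiquitin ligase MARCH3 (3.15 ± 0.19), ALDH8A1 (3.05 ± 0.16), the myosin MYO1G (3.02 ± 0.24) and CCDC168 (3.00 ± 0.15) completed the 8 largest increases. The largest decreases were those of DHFR2 (-2.93 ± 0.11), the mitochondrial peptidase MIPEP (-2.84 ± 0.13), the synaptic scaffold gene DLGAP2 (-2.75 ± 0.15), C4orf50 (-2.68 ± 0.14), the myosin MYO1C (-2.60 ± 0.15), the aminopeptidase LAP3 (-2.48 ± 0.13), the sterol reductase TM7SF2 (-2.25 ± 0.16) and the galactokinase GALK1 (-2.25 ± 0.18). Exons of ALDH8A1, CCDC168, DHFR2, MIPEP, DLGAP2, C4orf50 and TM7SF2 overlap another gene, so their counts are uncertain.

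Lists of cholesterol and fatty acid synthesis, ER chaperones and ATF4 targets fell with indisulam, while glycolysis, oxidative phosphorylation and the secretory granule list were not called (adjusted p = 0.161, 0.313 and 0.922). Of 25 genes of cholesterol synthesis and uptake, 22 fell (22 adjusted over the list alone) and none rose, with a median log2 change of -0.71. They included HSD17B7 (-1.79 ± 0.09), SREBF2, the transcription factor of the pathway (-1.36 ± 0.07), HMGCS1 (-0.97 ± 0.07) and INSIG1 (-1.05 ± 0.08). The camera test gave an adjusted p = 2.4e-09, and an adjusted p = 0.377 with an estimated correlation. In fatty acid synthesis 10 of 14 genes fell (10 adjusted over the list alone) and 1 rose, among them ACACA, the acetyl-CoA carboxylase (-1.34 ± 0.06), and ACSS2 (-1.43 ± 0.09), with an adjusted p = 0.000581 (adjusted p = 0.438 with an estimated correlation). ER chaperones and genes of the unfolded protein response had 22 of 24 members lower (22 adjusted over the list alone) and 1 higher, such as HYOU1 (-1.47 ± 0.09), CALR (-1.21 ± 0.09) and CANX (-0.96 ± 0.07), with an adjusted p = 9.78e-09 (adjusted p = 0.438 with an estimated correlation). Targets of ATF4 had 24 of 35 members lower (26 adjusted over the list alone) and 2 higher, with SHMT2 at -1.36 ± 0.09 and MARS, the methionyl-tRNA synthetase, at -1.27 ± 0.07 (adjusted p = 1.77e-05, and adjusted p = 0.481 with an estimated correlation).

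Growth lists moved in both directions. DNA replication genes fell in 32 of 49 cases (33 adjusted over the list alone) and rose in 5, with POLA1, the catalytic subunit of polymerase alpha, at -1.50 ± 0.08, CDC6 at -1.34 ± 0.08 and TYMS at -1.28 ± 0.08 (adjusted p = 7.5e-06, and adjusted p = 0.509 with an estimated correlation). p53 targets rose in 27 of 33 cases (28 adjusted over the list alone) and fell in 4, with a median of 0.66, and MDM2, the ligase that degrades p53, was at 1.06 ± 0.07, EDA2R at 1.41 ± 0.09 and PLK2 at 1.50 ± 0.10 (adjusted p = 2.65e-08, and adjusted p = 0.11 with an estimated correlation). Cytosolic ribosomal protein genes rose in 48 of 74 cases (48 adjusted over the list alone) and fell in 2, with a median of 0.21 (adjusted p = 9.11e-07, and adjusted p = 0.626 with an estimated correlation). Genes downstream of ERK rose in 13 of 24 cases (14 adjusted over the list alone) and fell in 1, with DUSP4 at 0.78 ± 0.06 and the cytokine LIF at 1.73 ± 0.15 (adjusted p = 0.000581, and adjusted p = 0.378 with an estimated correlation). Mitosis genes were split, with 19 of 50 higher and 17 lower (19 and 18 adjusted over the list alone), and the list was not called (adjusted p = 0.923). MYCN, followed here because it fell in the other treatments, was at -0.00 ± 0.06 (adjusted p = 0.972).

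SR factor and core spliceosome lists rose with indisulam, while the hnRNP list, with 11 of 25 higher and 7 lower (11 and 8 adjusted over the list alone), was not called (adjusted p = 0.183). SR splicing factors had 9 of 14 members higher (9 adjusted over the list alone) and 1 lower, led by SRSF4 (0.60 ± 0.05) and SRSF8 (0.72 ± 0.06), with an adjusted p = 0.0028 (adjusted p = 0.481 with an estimated correlation). The core spliceosome had 25 of 50 higher and 7 lower (29 and 8 adjusted over the list alone). PRPF3 was at 1.09 ± 0.06, DHX15 at 0.72 ± 0.06 and EFTUD2, a GTPase of the U5 particle, at -0.60 ± 0.06 (list adjusted p = 0.00146, and adjusted p = 0.626 with an estimated correlation). Mitochondrially encoded mRNAs had 12 of 13 members higher (13 adjusted over the list alone), such as MT-CYB (0.58 ± 0.10), with an adjusted p = 0.0017 (adjusted p = 0.626 with an estimated correlation), and the adjusted p was 0.151 with the GC and length trends removed (0.000686 to 0.151 over its alternatives). Nonsense-mediated decay factors had 9 of 16 higher and 3 lower (9 and 3 adjusted over the list alone), replication-dependent histones 16 of 39 lower and 3 higher (16 and 3), and repair genes of homologous recombination and the Fanconi pathway 20 of 41 lower and 9 higher (20 and 10), with adjusted p = 0.0337, 0.0305 and 0.0365 and, with an estimated correlation, adjusted p = 0.481, 0.626 and 0.626. These last calls ended when DMSO replicate 1 or indisulam replicate 2 (decay factors, adjusted p = 0.0582 and 0.0577), DMSO replicate 3 (histones, 0.0839) or DMSO replicate 3 or indisulam replicate 3 (repair genes, 0.0584 and 0.0523) was left out. Over all alternatives the adjusted p ranged from 0.0074 to 0.0582 for the decay factors, from 0.0074 to 0.0839 for histones and from 0.0171 to 0.0601 for repair genes. Polyadenylated RNA was sequenced, so the histone counts cover only polyadenylated histone RNA and need not follow histone mRNA as a whole.

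Alectinib against DMSO gave fewer changed genes than indisulam. The lists of mitosis, DNA replication, ER chaperones and adrenergic transcription factors fell, and the p53 list rose. Most adrenergic and p53 members were not called themselves, and with an estimated correlation 0 of 31 lists were called. The single genes HSPA6, GDF15, EGR1 and FOS rose, while the heat shock, ATF4 and ERK lists were not called (adjusted p = 0.1, 0.835 and 0.256). The edgeR test called 2242 genes higher and 2767 lower (44.8% higher), and with upper-quartile scaling it called 3285 higher and 1848 lower (64.0% higher), so the balance of directions depended on the scaling. At least 2-fold changes were 629 higher and 123 lower. Among protein-coding genes, with the same genes left out as for indisulam, they were 270 and 88. HSPA6, an inducible heat shock gene with close relatives, rose from 0.154 ± 0.0994 to 18.6 ± 3.81 CPM (SD, n = 4), a log2 change of 6.90 ± 0.34 (SE, adjusted p = 1.03e-11). The stress cytokine GDF15 (2.75 ± 0.30), the immediate early gene EGR1 (2.38 ± 0.23), KIAA1324 (2.32 ± 0.20), OVGP1 (2.19 ± 0.15), CYP4F3 (2.13 ± 0.19), COL11A2 (1.76 ± 0.16) and CMYA5 (1.74 ± 0.17) followed. TXNIP, a glucose-responsive regulator of thioredoxin, fell from 81.3 ± 6.17 to 23.9 ± 3.48 CPM (-1.77 ± 0.11), followed by GALK1 (-1.67 ± 0.18), the glucose-6-phosphate transporter SLC37A4 (-1.57 ± 0.14), MFSD3 (-1.50 ± 0.15), PAQR6 (-1.46 ± 0.14), SRPX2 (-1.42 ± 0.22), the tetraspanin CD9 (-1.42 ± 0.14) and RELL2 (-1.30 ± 0.14). KIAA1324, SLC37A4, PAQR6, SRPX2 and RELL2 share exonic sequence with a gene on the other strand, so their counts are uncertain. Leaving out the deepest library, alectinib replicate 1, gave 4116 changed genes in place of 5009.

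The mitosis and DNA replication lists had the lowest adjusted p in alectinib with the preset correlation. Of 50 mitosis genes, 47 fell (49 adjusted over the list alone) and none rose, with a median of -0.39, and examples were the separase gene ESPL1 (-0.70 ± 0.06), MYBL2 (-1.04 ± 0.10) and MKI67 (-0.59 ± 0.06), with an adjusted p = 3.31e-27 (adjusted p = 0.0569 with an estimated correlation). DNA replication genes fell in 40 of 49 cases (43 adjusted over the list alone). MCM4 was at -0.59 ± 0.06, PCNA at -0.59 ± 0.06 and TK1 at -1.02 ± 0.12 (list adjusted p = 5.06e-22, and adjusted p = 0.0631 with an estimated correlation). Recombination and Fanconi repair genes fell in 24 of 41 cases (26 adjusted over the list alone). FANCG was at -0.83 ± 0.09 (list adjusted p = 4.21e-10, and adjusted p = 0.0569 with an estimated correlation). Ribosome biogenesis genes fell in 16 of 41 cases (20 adjusted over the list alone, with 1 rise). NOLC1 was at -0.50 ± 0.05 (list adjusted p = 8.13e-06, and adjusted p = 0.378 with an estimated correlation).

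Adrenergic, catecholamine and fibroblast lists fell with alectinib as well, while the ERK list was not called. Adrenergic transcription factors of neuroblastoma fell in 10 of 24 cases (13 adjusted over the list alone), including MYCN, the amplified oncogene of this line (-0.45 ± 0.06), and SOX11 (-0.34 ± 0.05), with an adjusted p = 0.000122 (adjusted p = 0.215 with an estimated correlation). Genes of catecholamine synthesis and secretory granules fell in 12 of 28 cases (12 adjusted over the list alone), led by STMN2 (-1.20 ± 0.12) and MAOA (-0.70 ± 0.09), with an adjusted p = 5.01e-05 (adjusted p = 0.0985 with an estimated correlation). Fibroblast markers fell in 5 of 7 cases (6 adjusted over the list alone), such as LUM (-1.49 ± 0.18), with an adjusted p = 0.000388 (adjusted p = 0.0569 with an estimated correlation). Of 24 genes downstream of ERK, 4 rose and 2 fell (5 and 2 adjusted over the list alone) and the list was not called (adjusted p = 0.256), with EGR1 and FOS (2.48 ± 0.27) up and CCND1 (-0.58 ± 0.05) and SPRED2 (-0.29 ± 0.07) down.

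Stress lists divided in alectinib. ER chaperones fell in 18 of 24 cases (20 adjusted over the list alone) and rose in 2, with PDIA4 at -0.89 ± 0.08 and MANF at -0.92 ± 0.10 (adjusted p = 6.35e-11, and adjusted p = 0.169 with an estimated correlation). p53 targets rose in 14 of 33 cases (15 adjusted over the list alone) and fell in 1, with BTG2, an antiproliferative gene, at 0.93 ± 0.10 (adjusted p = 1e-05, and adjusted p = 0.0844 with an estimated correlation). In the cytosolic heat shock list, 5 of 22 rose and 1 fell (7 and 1 adjusted over the list alone). HSPA1B was at 1.43 ± 0.15, DNAJB1 at 0.82 ± 0.11 and BAG3 at 0.92 ± 0.15, and the list was not called (list adjusted p = 0.1). Oxidative phosphorylation (11 of 49 lower, 2 higher, and as many adjusted over the list alone), cholesterol synthesis (9 of 25 lower, 1 higher, with 11 and 1 adjusted over the list alone), glycolysis (9 of 31 lower, 1 higher, with 10 and 1), fatty acid synthesis (4 of 14 lower, with 6) and hnRNP proteins (10 of 25 lower, with 10) had adjusted p = 0.00107, 0.00335, 0.00787, 0.0311 and 0.0114 and, with an estimated correlation, adjusted p = 0.671, 0.584, 0.672, 0.584 and 0.649. All 5 calls ended under at least 1 alternative, with the highest adjusted p at 0.0731, 0.0551, 0.0799 (without DMSO replicate 1), 0.328 and 0.337 and the lowest at 3.32e-06, 0.000505, 3.22e-07, 0.0192 and 0.00248. The fatty acid call also ended without DMSO replicate 2 (0.0507) or alectinib replicate 1 (0.134), and the hnRNP median of -0.07 became 0.01 with upper-quartile scaling.

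The combination against DMSO asked what both drugs did together. All 33 p53 targets rose, and the ribosomal protein, heat shock, SR factor and core spliceosome lists rose, while DNA replication, lipid synthesis and adrenergic identity genes fell. With an estimated correlation only the p53 list was called. The edgeR test called 6657 genes higher and 6870 lower, of which 2630 and 2515 changed at least 2-fold. Upper-quartile scaling gave 8027 higher and 5776 lower and moved the median change of all genes from 0.01 to 0.13, and the changes given here are relative to TMM scaling. Among protein-coding genes, with the same genes left out as for indisulam, 1100 were called at least 2-fold higher and 1863 lower. HSPA6 reached 54.4 ± 22.5 CPM (SD, n = 4), a log2 change of 8.44 ± 0.34 (SE, adjusted p = 1.71e-15). RAB44, which starts 10471 bp downstream of CDKN1A on chromosome 6 (36697810 to 36733183), rose from 0.136 ± 0.0737 to 21.8 ± 3.73 CPM (7.29 ± 0.24). Next were GDF15 (6.35 ± 0.28), CYP4F3 (6.33 ± 0.17), OVGP1 (5.00 ± 0.15), DCAF4L1 (4.78 ± 0.14), the adhesion gene NECTIN4 (4.76 ± 0.18) and CCDC168 (4.57 ± 0.15). The lowest were GALK1 (-3.52 ± 0.20), C4orf50 (-3.42 ± 0.15), MYO1C (-3.21 ± 0.15), DLGAP2 (-3.08 ± 0.16), RELN, which encodes an extracellular guidance protein of neurons (-2.96 ± 0.23), MIPEP (-2.91 ± 0.13), LAP3 (-2.87 ± 0.14) and the replication factor CDC45 (-2.82 ± 0.14). CCDC168, C4orf50, DLGAP2 and MIPEP overlap exons of other genes.

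In the combination the p53 list had the largest median, 1.77, with 33 of 33 members higher (33 adjusted over the list alone). MDM2 (2.24 ± 0.07), BTG2 (3.08 ± 0.10), the death receptor gene TNFRSF10B (1.96 ± 0.07) and PLK2 (2.75 ± 0.10) led it, and the camera test gave an adjusted p = 7.55e-19, and an adjusted p = 0.00353 with an estimated correlation. CDKN1A, the cell cycle inhibitor p21 (chromosome 6, 36676460 to 36687339, plus strand), was chosen for its place next to RAB44 after its values were seen, and it rose from 142 ± 9.81 to 1266 ± 312 CPM (3.16 ± 0.12). Among regulators of apoptosis, 13 of 28 rose and 6 fell (13 and 6 adjusted over the list alone). BBC3, which encodes the p53-induced protein PUMA, was at 2.69 ± 0.14 and BAX at 1.05 ± 0.10, and the list was not called (list adjusted p = 0.315). Genes downstream of ERK rose in 15 of 24 cases and fell in 3 (16 and 3 adjusted over the list alone). LIF was at 3.42 ± 0.15, EGR1 at 3.82 ± 0.23 and FOS at 3.99 ± 0.28 (list adjusted p = 0.000179, and adjusted p = 0.181 with an estimated correlation). NUPR1, a stress-induced gene of the ATF4 list, rose by 7.94 ± 0.41 from 0.0528 ± 0.0668 CPM, while 10 of the 35 list members rose and 17 fell (10 and 17 adjusted over the list alone, list adjusted p = 0.345).

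Ribosomal protein, heat shock, SR factor and core spliceosome lists rose in the combination, while the hnRNP list, with 9 of 25 higher and 9 lower (9 and 9 adjusted over the list alone), was not called (adjusted p = 0.909). Ribosomal protein genes were higher in 70 of 74 cases (71 adjusted over the list alone), with a median of 0.59 and RPS23 at 1.31 ± 0.06 (adjusted p = 1.56e-16, and adjusted p = 0.329 with an estimated correlation). Heat shock genes were higher in 17 of 22 cases (17 adjusted over the list alone). DNAJB1 was at 1.86 ± 0.11, HSPA1B at 2.38 ± 0.15 and BAG3 at 2.31 ± 0.15 (list adjusted p = 4.92e-06, and adjusted p = 0.181 with an estimated correlation). SR factors were higher in 11 of 14 cases (11 adjusted over the list alone). SRSF8 was at 1.16 ± 0.06 (list adjusted p = 0.000127, and adjusted p = 0.213 with an estimated correlation). The core spliceosome had 35 of 50 higher and 7 lower (35 and 7 adjusted over the list alone). PRPF3 was at 2.00 ± 0.06 and EFTUD2 at -1.32 ± 0.06 (list adjusted p = 9.09e-06, and adjusted p = 0.333 with an estimated correlation).

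Proliferation and lipid lists also fell in the combination. DNA replication genes were lower in 39 of 49 cases and higher in 5 (39 and 6 adjusted over the list alone). POLA1 was at -2.19 ± 0.08 and RRM2, the ribonucleotide reductase subunit, at -1.95 ± 0.07 (list adjusted p = 3.61e-09, and adjusted p = 0.213 with an estimated correlation). Mitosis genes were lower in 33 of 50 cases and higher in 6 (33 and 6 adjusted over the list alone), with TOP2A at -2.01 ± 0.07 (adjusted p = 8.15e-05, and adjusted p = 0.468 with an estimated correlation), and repair genes were lower in 27 of 41 and higher in 5 (27 and 5 adjusted over the list alone). FANCI was at -1.77 ± 0.07 and BRCA1 at -1.10 ± 0.06 (list adjusted p = 8.71e-06, and adjusted p = 0.181 with an estimated correlation). Cholesterol genes were lower in 21 of 25 cases (21 adjusted over the list alone). LSS was at -1.70 ± 0.10 (list adjusted p = 1.73e-07, and adjusted p = 0.208 with an estimated correlation). Fatty acid genes were lower in 12 of 14 and higher in 1 (12 and 1 adjusted over the list alone). ACLY was at -2.16 ± 0.09 (list adjusted p = 1.16e-05, and adjusted p = 0.181 with an estimated correlation). ER chaperones were lower in 19 of 24 and higher in 4 (19 and 4 adjusted over the list alone). CANX was at -1.79 ± 0.07 (list adjusted p = 1.94e-05, and adjusted p = 0.333 with an estimated correlation). Adrenergic transcription factors were lower in 18 of 24 and higher in 1 (18 and 1 adjusted over the list alone). MYCN fell from 2443 ± 101 to 1294 ± 99.6 CPM (list adjusted p = 0.000179, and adjusted p = 0.213 with an estimated correlation).

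The remaining called lists completed the combination. Ribosome biogenesis genes were lower in 25 of 41 cases and higher in 7 (25 and 7 adjusted over the list alone). UTP4 was at -1.73 ± 0.07 (list adjusted p = 0.00408, and adjusted p = 0.496 with an estimated correlation). Glycolysis genes were lower in 22 of 31 and higher in 5 (23 and 5 adjusted over the list alone). PFKM, a phosphofructokinase, was at -1.44 ± 0.07 (list adjusted p = 0.00879, and adjusted p = 0.654 with an estimated correlation). Fibroblast markers were lower in 5 of 7 cases (5 adjusted over the list alone, with 1 higher), such as PDGFRB (-1.42 ± 0.12), mitochondrially encoded mRNAs were higher in 8 of 13 (8 adjusted over the list alone), and decay factors higher in 10 of 16 and lower in 4 (10 and 4 adjusted over the list alone). Their adjusted p was 0.0384, 0.0238 and 0.0444, and with an estimated correlation adjusted p = 0.181, 0.654 and 0.333. With the GC and length trends removed the adjusted p of the first pair was 0.0815 and 0.655 (over all alternatives 0.0284 to 0.0815 and 0.0145 to 0.655), and that of the decay factors was 0.0669 without DMSO replicate 1 and 0.0616 without combination replicate 2 (0.00756 to 0.0669).

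**Figure D3:**
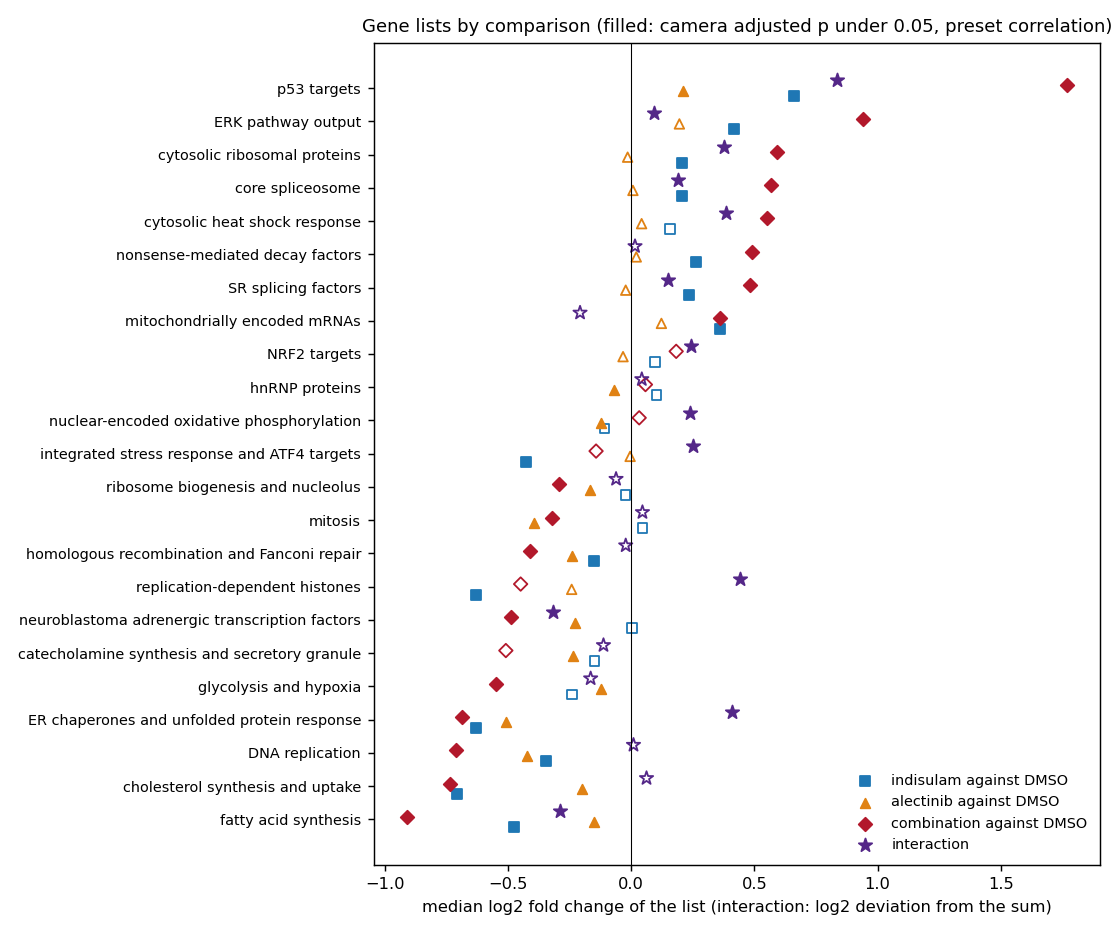
Median log2 fold change of each gene list called in at least 1 of the comparisons shown (marker lists of other cell types left out), for indisulam, alectinib and the combination against DMSO and for the interaction. Filled symbols mark an adjusted p under 0.05 with the preset correlation, and the p53 list, at 1.77 in the combination and 0.84 in the interaction, lies farthest to the right.

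The combination was also compared with each single drug, which asked what the second drug added. Adding alectinib to indisulam gave 4249 genes higher and 4502 lower, and adding indisulam to alectinib gave 5939 higher and 6512 lower. Upper-quartile scaling turned both balances, with 4852 and 3959, and 6453 and 6073. Against indisulam, HSPA6 (7.85 ± 0.32), GDF15 (3.60 ± 0.23), RAB44 (3.49 ± 0.17) and EGR1 (3.26 ± 0.22) were the highest, and DOK3 (-2.09 ± 0.14), RAMP2 (-1.96 ± 0.15), the homeobox gene DLX5 (-1.94 ± 0.14) and BNC2 (-1.87 ± 0.18) the lowest. Against alectinib, RAB44 (5.84 ± 0.20), CYP4F3 (4.19 ± 0.14), NECTIN4 (3.85 ± 0.17) and DCAF4L1 (3.75 ± 0.13) were the highest, and SGK494 (-2.75 ± 0.15), MYO1C (-2.71 ± 0.15), LAP3 (-2.60 ± 0.13) and C4orf50 (-2.56 ± 0.15) the lowest. DOK3, RAMP2, BNC2, SGK494 and C4orf50 overlap exons of other genes.

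Against indisulam, all 33 p53 targets rose (33 adjusted over the list alone). BTG2 was at 2.40 ± 0.10 and FDXR at 1.86 ± 0.10 (list adjusted p = 1.79e-27, and adjusted p = 0.000602 with an estimated correlation). Adrenergic transcription factors fell in 19 of 24 cases (19 adjusted over the list alone, with 1 rise). MYCN was at -0.91 ± 0.06 and KLF7 at -0.87 ± 0.06 (list adjusted p = 3.21e-09, and adjusted p = 0.0764 with an estimated correlation). Mitosis genes fell in 36 of 50 cases and rose in 1 (39 and 1 adjusted over the list alone). MKI67 was at -0.94 ± 0.06 (list adjusted p = 8.5e-13, and adjusted p = 0.212 with an estimated correlation). Heat shock genes rose in 16 of 22 cases (16 adjusted over the list alone, with 1 fall). DNAJB1 was at 1.63 ± 0.11 (list adjusted p = 1.33e-06, and adjusted p = 0.183 with an estimated correlation). ATF4 targets rose in 18 of 35 cases and fell in 7 (18 and 7 adjusted over the list alone). ATF3 was at 2.73 ± 0.12 and PPP1R15A, which encodes a phosphatase subunit that ends the stress response, at 2.80 ± 0.17 (adjusted p = 0.0143, and adjusted p = 0.666 with an estimated correlation), a call that ended without combination replicate 2 (list adjusted p = 0.0569, range over alternatives 0.00247 to 0.0569).

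Other lists also moved against indisulam, where 16 of 31 lists were called. Ribosomal protein genes rose in 68 of 74 cases (70 adjusted over the list alone), with RPL22 at 0.73 ± 0.06. Their adjusted p was 5.18e-18, with adjusted p = 0.318 with an estimated correlation. DNA replication genes fell in 34 of 49 cases and rose in 2 (35 and 2 adjusted over the list alone). RRM2 was at -1.07 ± 0.07 (list adjusted p = 1.89e-10, and adjusted p = 0.212 with an estimated correlation). Repair genes fell in 25 of 41 cases and rose in 1 (29 and 2 adjusted over the list alone). BRCA2 was at -1.06 ± 0.10 (list adjusted p = 7e-08, and adjusted p = 0.0764 with an estimated correlation). Ribosome biogenesis genes fell in 21 of 41 cases and rose in 3 (22 and 3 adjusted over the list alone). UTP20 was at -0.93 ± 0.07 (list adjusted p = 5.29e-05, and adjusted p = 0.37 with an estimated correlation). Fatty acid genes fell in 11 of 14 cases (11 adjusted over the list alone). ACLY was at -1.33 ± 0.09 (list adjusted p = 8.73e-05, and adjusted p = 0.212 with an estimated correlation).

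Core spliceosome genes rose in 28 of 50 cases against indisulam and fell in 4 (30 and 4 adjusted over the list alone). PRPF3 was at 0.91 ± 0.06 (list adjusted p = 5.42e-05, and adjusted p = 0.392 with an estimated correlation). SR factors rose in 7 of 14 cases (7 adjusted over the list alone), with SRSF5 at 0.53 ± 0.06, and fibroblast markers fell in 4 of 7 (4 adjusted over the list alone), with LUM at -1.51 ± 0.18. Both had an adjusted p of 0.00705, and with an estimated correlation adjusted p = 0.37 and 0.0764. Catecholamine and granule genes fell in 14 of 28 cases and rose in 3 (15 and 3 adjusted over the list alone), with CHGA at -0.95 ± 0.11. ERK genes rose in 12 of 24 and fell in 2 (12 and 4 adjusted over the list alone), with EGR1 up and CCND1 at -0.74 ± 0.05. Glycolysis genes fell in 14 of 31 and rose in 4 (14 and 4 adjusted over the list alone), with GPI at -0.72 ± 0.07. These 3 lists had adjusted p = 0.00705, 0.0142 and 0.0171, and with an estimated correlation adjusted p = 0.316, 0.328 and 0.712. The first pair ended under the stricter filter (0.0622 and 0.561, over all alternatives 0.00165 to 0.0622 and 0.00728 to 0.561), and glycolysis without combination replicate 1 (0.0503, range 0.00784 to 0.0503).

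Against alectinib, 11 of 31 lists were called. Ribosomal protein genes rose in 73 of 74 cases (74 adjusted over the list alone), with RPS23 at 0.83 ± 0.06 (adjusted p = 3.88e-21, and adjusted p = 0.343 with an estimated correlation). p53 targets rose in 31 of 33 cases (32 adjusted over the list alone). MDM2 was at 2.11 ± 0.07 and PPM1D, a phosphatase that restrains p53, at 1.38 ± 0.06 (list adjusted p = 1.41e-20, and adjusted p = 0.00254 with an estimated correlation). Cholesterol genes fell in 20 of 25 cases (21 adjusted over the list alone). HMGCS1 was at -1.10 ± 0.07 (list adjusted p = 2.12e-06, and adjusted p = 0.321 with an estimated correlation). Mitosis genes were split, with 19 of 50 higher, such as CCNB1 (1.18 ± 0.06), and 17 lower, such as TOP2A (-1.62 ± 0.07), or 20 and 18 adjusted over the list alone, and the list was not called (adjusted p = 0.66).

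Heat shock, core spliceosome and SR factor lists rose against alectinib, while the ATF4 and ER chaperone lists were not called (adjusted p = 0.396 and 0.0882). Heat shock genes rose in 20 of 22 cases (21 adjusted over the list alone). HSPA4 was at 0.98 ± 0.06 (list adjusted p = 4e-06, and adjusted p = 0.279 with an estimated correlation). The core spliceosome had 34 of 50 higher and 9 lower (34 and 9 adjusted over the list alone). PRPF3 was at 1.11 ± 0.06 (list adjusted p = 1.14e-05, and adjusted p = 0.468 with an estimated correlation). SR factors rose in 12 of 14 cases (12 adjusted over the list alone). SRSF4 was at 0.74 ± 0.05 (list adjusted p = 4.32e-05, and adjusted p = 0.279 with an estimated correlation). ERK genes rose in 16 of 24 and fell in 3 (16 and 3 adjusted over the list alone). LIF was at 2.84 ± 0.15 (list adjusted p = 5.15e-05, and adjusted p = 0.279 with an estimated correlation). Fatty acid genes fell in 10 of 14 and rose in 1 (10 and 1 adjusted over the list alone). ACACA was at -1.51 ± 0.06 (list adjusted p = 6.45e-05, and adjusted p = 0.279 with an estimated correlation). DNA replication genes fell in 31 of 49 and rose in 11 (31 and 11 adjusted over the list alone). POLA1 was at -1.67 ± 0.08 and ORC6 at 1.03 ± 0.06 (list adjusted p = 0.00154, and adjusted p = 0.631 with an estimated correlation). Adrenergic factors fell in 17 of 24 and rose in 1 (17 and 1 adjusted over the list alone), and repair genes fell in 19 of 41 and rose in 9 (19 and 9 adjusted over the list alone), with MYCN at -0.47 ± 0.06 and FANCI at -1.34 ± 0.07. Their adjusted p was 0.0117 and 0.0456, and with an estimated correlation adjusted p = 0.468 and 0.523. The adrenergic call ended with the GC and length trends removed (0.0861, range 0.0045 to 0.0861), and the repair call under 7 alternatives, among them those without alectinib replicate 4 (0.0562), combination replicate 2 (0.0522) and combination replicate 4 (0.0802, range 0.0241 to 0.0802).

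The interaction asked where the combination departed from the sum of the single-drug changes. The title speaks of synergy, and a departure from a sum of log2 mRNA changes need not be what it means by that word. The p53 and ribosomal protein lists rose beyond the sum, and the lists of adrenergic transcription factors and fatty acid synthesis lay below it. The ER chaperone and ATF4 lists also lay above the sum, although most ATF4 members were not called themselves. In the combination the ER chaperone list fell (median -0.69) and the ATF4 list was not called (10 higher, 17 lower). With an estimated correlation only the p53 list was called. The edgeR test called 1537 genes above and 1488 below the sum, against 1352 and 1827 with upper-quartile scaling and 76 and 18 when tested against a log2 change of 0.5, so this balance depended on the choice. RAB44 (2.04 ± 0.41), NECTIN4 (1.95 ± 0.24), ZNF750 (1.90 ± 0.21), ZNF385A (1.82 ± 0.24), PIDD1, a p53-induced death domain gene (1.68 ± 0.19), and ATF3 (1.67 ± 0.17) lay farthest above. Farthest below were PDZD7 (-1.49 ± 0.26), OVGP1 (-1.30 ± 0.19), PRTG (-1.24 ± 0.13), SLC26A10 (-1.22 ± 0.22), ARHGAP33 (-1.16 ± 0.19) and SGK494 (-1.16 ± 0.20). OVGP1 still rose in each treatment, so its value below the sum was a smaller rise than the single drugs added up to. PIDD1, PDZD7, PRTG, SLC26A10, ARHGAP33 and SGK494 overlap exons of other genes.

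Of the 33 p53 targets, 30 lay above the sum (31 adjusted over the list alone) with a median of 0.84, including FDXR (1.60 ± 0.14), BTG2 (1.47 ± 0.13), MDM2 (1.04 ± 0.10) and PPM1D (0.82 ± 0.08), with an adjusted p = 3.98e-34 (adjusted p = 0.000204 with an estimated correlation). Ribosomal protein genes lay above in 57 of 74 cases (70 adjusted over the list alone). RPS16 was at 0.45 ± 0.08 (list adjusted p = 1.43e-25, and adjusted p = 0.388 with an estimated correlation). ER chaperones lay above in 14 of 24 cases and below in 1 (16 and 1 adjusted over the list alone). EDEM1 was at 0.74 ± 0.11 and XBP1 at 0.73 ± 0.13, although the list fell in the combination itself (list adjusted p = 1.36e-08, and adjusted p = 0.388 with an estimated correlation). ATF4 targets lay above in 12 of 35 cases and below in 1 (14 and 2 adjusted over the list alone). PPP1R15A was at 1.48 ± 0.23 and DDIT3, which encodes the stress factor CHOP, at 1.10 ± 0.18 (list adjusted p = 1.57e-05, and adjusted p = 0.427 with an estimated correlation). Adrenergic transcription factors lay below in 13 of 24 cases (14 adjusted over the list alone). KLF7 was at -0.53 ± 0.08 and MYCN at -0.47 ± 0.09 (list adjusted p = 1.57e-06, and adjusted p = 0.279 with an estimated correlation). Heat shock genes lay above in 11 of 22 cases (13 adjusted over the list alone). HSPA4L was at 0.82 ± 0.12 (list adjusted p = 1.33e-06, and adjusted p = 0.279 with an estimated correlation). Oxidative phosphorylation genes lay above in 16 of 49 cases and below in 1 (23 and 1 adjusted over the list alone). COX6B1 was at 0.50 ± 0.10 (list adjusted p = 1.57e-06, and adjusted p = 0.483 with an estimated correlation). Fatty acid genes lay below in 7 of 14 cases (7 adjusted over the list alone). ACLY was at -0.89 ± 0.12 (list adjusted p = 0.00268, and adjusted p = 0.427 with an estimated correlation).

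The remaining lists called in the interaction also departed from the sum. Core spliceosome genes lay above it in 16 of 50 cases and below in 6 (21 and 6 adjusted over the list alone), with PHF5A at 0.68 ± 0.13 and EFTUD2 at -0.51 ± 0.08. SR factors lay above in 4 of 14 cases (5 adjusted over the list alone), with SRSF2 at 0.49 ± 0.10. Both had an adjusted p of 0.00105, and with an estimated correlation adjusted p = 0.593 and 0.427. Histone genes lay above in 3 of 39 cases (3 adjusted over the list alone), although in the combination 17 were lower and 5 higher (17 and 5 adjusted over the list alone) and the list was not called (adjusted p = 0.428). HIST1H1C was at 0.77 ± 0.18 (list adjusted p = 0.000985, and adjusted p = 0.427 with an estimated correlation). Here too the histone counts cover only polyadenylated RNA. NRF2 targets lay above in 5 of 22 cases (7 adjusted over the list alone), with AKR1C1 at 1.13 ± 0.23, and ERK genes in 4 of 24 (5 adjusted over the list alone), with LIF at 1.10 ± 0.21. Their adjusted p was 0.00799 and 0.0453, and with an estimated correlation adjusted p = 0.593 and 0.483. The stricter filter ended both (0.209, range 0.000754 to 0.209, and 0.504, range 0.0141 to 0.504). The ERK call also ended without DMSO replicate 4 (0.0693), indisulam replicate 3 (0.0925), alectinib replicates 2 or 3 (0.188 and 0.0815), or combination replicates 2 or 4 (0.0862 and 0.0658). The apoptosis list was not called (adjusted p = 0.339), with PMAIP1, which encodes NOXA, at 0.97 ± 0.10 and BBC3 at 1.23 ± 0.19. Across the 16025 genes called in any treatment against DMSO, the combination changed by 0.848 of the sum of the single-drug log2 changes (0.901 with a prior count of 2). Of these genes, 52.0% lay beyond their sum and 9.73% changed in the opposite direction, against 44.5% and 16.7% of all 22433 tested genes (slope 0.800). Errors of the single-drug changes enter the sum and lower such a slope even under exact additivity. The slope expected under additivity was not computed, so these slopes do not show that the combination fell short of the sum.

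Both single drugs were also compared with each other through the genes they shared. Among genes called in both, 2324 changed in the same direction (941 higher and 1383 lower) and 831 in opposite directions. Independent lists of these sizes would share 516 higher and 687 lower genes, with 1194 in opposite directions. The 20 simulations of unchanged groups against the same DMSO libraries gave 0 shared genes on average. With no changed gene in them, hardly any call could be shared, so this count is no benchmark for drugs that change many genes. With DMSO libraries split between the drugs, the median over the 6 splits was 1281.5 genes in the same direction and 416.5 in opposite directions. The median was 477.5 for genes higher in both and 804 for genes lower in both. Independent lists of the sizes in those splits would share a median of 232 higher and 367 lower genes, with 584 in opposite directions. The covariance of the log2 changes was 0.149, against 0.0543 in the simulations and 0.114 with split controls, and the correlation across genes was 0.311, against 0.514 and 0.189. Genes are not independent replicates, so these correlations carry no p.

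Gene structure was examined because the study concerns splicing, although counts per gene cannot show isoforms. Protein-coding genes in the longest 20% of genomic span (2943 genes of at least 104524 bp) had a median log2 change of -0.27 in the combination, against -0.04 for the other genes (adjusted p = 0.00198, and adjusted p = 0.232 with an estimated correlation), with 1470 lower and 562 higher. Their median interaction was -0.12 (adjusted p = 1.14e-05, and adjusted p = 0.158 with an estimated correlation), and that of the shortest 20% was 0.14 (adjusted p = 0.00021, and adjusted p = 0.459 with an estimated correlation). The set of 331 single-exon genes shifted upwards in the combination, with a median of 0.15 (adjusted p = 0.00198, and adjusted p = 0.232 with an estimated correlation). Not all of them rose, and the quartiles over the 329 with a transcript sequence were -0.335 and 0.794. In all, 12 of 18 set tests passed with the preset correlation and none with an estimated one.

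**Figure D4:**
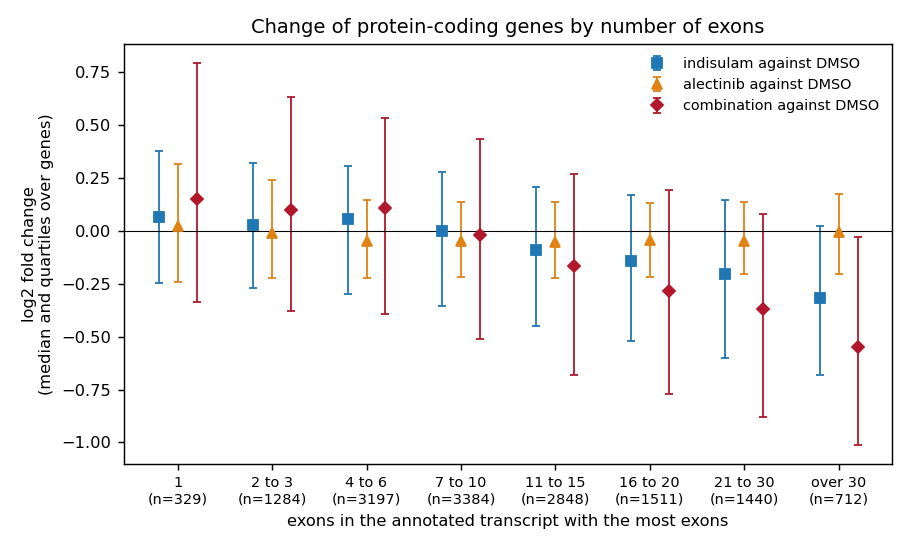
Log2 fold change of protein-coding genes by the number of exons in the annotated transcript with the most exons, for indisulam, alectinib and the combination against DMSO, with points for medians and bars for the quartiles over genes. The combination median went from 0.15 in single-exon genes to -0.55 in genes with over 30 exons.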

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

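A closer look was given to libraries that lay far from the other 3 of their group and to a difference in response between groups. The rule for single libraries was Dixon's test at the 95% level, and 8 of the 52 groups of 4 tested had such a library, where chance would give about 1 in 20, or 2.6. Alectinib replicate 1 had 90.2 M counts (M, 1e6), 6.73% mitochondrial counts and 8.0% of its counts in its 10 most abundant genes. Mitochondrial counts were 5.77% in DMSO replicate 3 and 6.41% in combination replicate 4. MDM2 was at 113 CPM in DMSO replicate 3, GDF15 at 1.82 CPM in alectinib replicate 2 and TXNIP at 32.5 CPM in combination replicate 2. The response to alectinib differed with and without indisulam for 3025 genes, by the test of the interaction.

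A first pattern was that p53 targets such as MDM2 and BTG2 rose in the combination beyond the sum of the single drugs. The explanations tested after the data were seen were technical: with the GC and length trends removed the median interaction was 0.839, its lowest value over the 16 fits without 1 library was 0.805, and the lower of the medians under the other scalings was 0.796. These values argue against all 3. A biological explanation, that p53 is activated more strongly when both drugs are present, was not tested, because protein was not measured.

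A second pattern was that genes with more exons fell in the combination, with a Spearman correlation of -0.24. Its value was -0.225 given transcript length, GC content and mean CPM, -0.195 given genomic span, and -0.231 in the fit without 1 library that lay closest to 0. These tests were chosen after the data were seen, and they argue against these technical explanations. The trend was not particular to the combination. In indisulam alone the correlation was -0.18, with -0.222 given transcript length, GC content and mean CPM, and -0.194 given genomic span. In alectinib alone it was -0.0168. For the interaction it was -0.208, and -0.0888 given span, transcript length, GC content and mean CPM. No biological explanation was tested, since the table holds 1 count per gene and shows no splice junctions.

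The last pattern was that strongly induced genes, such as RAB44 downstream of CDKN1A, often lay just downstream of another gene. The set tested was 1100 protein-coding genes called at least 2-fold higher in the combination. Genes named by rule were left out of it, RAB44 among them. A neighbour was a protein-coding gene ending within 15 kb upstream. Of the 1100 genes, 32.5% had one on the same strand, against a median of 28.2% in expression-matched genes (25.8% to 30.7%). On the opposite strand 18.7% had one, against 17.6% (15.5% to 19.7%). Among those with a neighbour on the same strand, 25.5% had exons that overlap another gene on that strand. The share was 16.3% of all genes considered, with or without such a neighbour, so the 2 shares are not like for like. Read-through, joint induction and shared exons were chosen after the data were seen, and these values for the combination leave all 3 open. Among induced genes, the share on the same strand was 39.3% in alectinib (matched 24.1% to 34.8%) and 31.2% in indisulam (24.9% to 33.0%). Among lowered genes it was 30.8% in indisulam, 31.8% in alectinib and 28.5% in the combination (matched upper limits 30.5%, 38.6% and 28.8%). On the opposite strand, 18.1% of genes induced by alectinib had a neighbour (matched 12.6% to 21.5%). The alectinib excess beyond the matched limits was therefore on the same strand only, which gives no sign of joint induction on either strand. The limits are wide, and joint induction on the same strand stays open. Exon overlap among induced genes with a same-strand neighbour was 20.8% in alectinib and 25.9% in indisulam, again not like for like with 16.3%.

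Whether chance could give as many changed genes was asked by regrouping the libraries. Only 1 of 35 splits, the real one, reached the number of genes for each comparison of 2 groups (10734, 5009, 13527, 8751 and 12451), and the highest other split gave 1, 1, 0, 6 and 0. For the interaction 1 of 100 splits, the real one, reached 3025, and the highest other gave 0. For the comparisons of 2 groups, the rank of the real split argues against labels unrelated to the counts, at that resolution. The low counts of the other splits show little more, because those splits mixed treatments and the drug effects entered their spread. For the interaction, regrouping also mixed the effects of the single drugs, so it cannot decide whether chance gave the departures from the sum.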

How the results depend on the processing

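Removal of the GC and length trends (12 of the 230 values recomputed) was chosen after the data were seen, and the other 218 were planned. Of the 230, 214 stayed on their side, 14 were weaker, 2 were stronger and none reversed. A test against a log2 change of 0.5 called 3535 (indisulam), 373 (alectinib), 6950 (combination), 1635 (combination against indisulam), 5160 (combination against alectinib) and 94 (interaction) genes, fewer by construction. The stricter filter, which tested 11417 genes, called 8837 in the combination. With an estimated correlation 0, 0, 1, 1, 1 and 1 lists were called in the same order. In that order fry called 23, 14, 25, 19, 24 and 9 lists, against 14, 14, 18, 16, 11 and 13 in the main test. Fry asks whether the members of a list changed at all, and camera whether they changed more than other genes. The 2 counts therefore answer different questions, and the cause of their differences was not tested. Split controls gave 1281.5 genes shared in the same direction, with 2 DMSO libraries in place of 4 for each drug. Leaving out 1 library gave 9800 to 10355, 3812 to 4813, 12939 to 13302, 7894 to 8511, 11732 to 12138 and 2264 to 3533 genes, 12 to 15, 13 to 15, 17 to 18, 16 to 18, 10 to 14 and 12 to 13 lists, and an additivity slope of 0.811 to 0.862. With the replicate number as a block the genes were 11044, 5490, 13738, 9110, 12752 and 3562, and the lists 13, 14, 17, 16, 10 and 12. Of 24 pairs of libraries with the same number, 5 correlated above 0.1 (-0.0626 to 0.168), and 9 of 16 libraries correlated best with their own number (median 0.0492, against -0.0104 for different numbers), a hint that numbers may be shared; the labels give no pairing, so none was used. With the trends removed the genes were 11605, 6625, 14179, 9793, 13197 and 4497. Among single-gene values, 4410 of 4452 kept their side, 19 were weaker, 22 stronger and 1 reversed: MT-ND3 in indisulam, at -0.0113 (adjusted p = 0.913) with the trends removed, and the cause was not tested. Against a log2 change of 0.5, 173 of 507 single-gene values were weaker. Without 1 library 4618 of 4680 single-gene values kept their side, 52 were weaker and 10 stronger. Of the list calls, 771 of 792 held without 1 library, 71 of 81 under the stricter filter and 78 of 86 with the trends removed. With the replicate block 82 of 86 held, and with an estimated correlation 4 of 86. Fry also called 79 of the 86, which is no check of them because fry asks another question. Depth was similar in 15 libraries, and it limits mainly genes with few counts.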

Other observations

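Zinc finger genes of the C2H2 family rose with indisulam, a result outside the lists of the report. Of 572 tested, 292 rose and 77 fell, with a median log2 change of 0.26 (adjusted p = 4.12e-08, and adjusted p = 0.0653 with an estimated correlation). ZNF557 rose by 2.30 ± 0.06 (SE), YY2 by 2.43 ± 0.15 and ZKSCAN7 by 1.23 ± 0.07, while PEG3 fell by 1.15 ± 0.07. In the combination 314 rose and 98 fell (median 0.28, adjusted p = 8.75e-06, and adjusted p = 0.168 with an estimated correlation). In alectinib 81 rose and 31 fell, and the family was not called (adjusted p = 0.205).

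More noncoding genes rose than fell in each treatment. Of 7705 tested, 1608 rose and 1040 fell in indisulam, 852 and 128 in alectinib and 2241 and 1097 in the combination. With alectinib, antisense genes had 260 of 2101 higher and 36 lower (median 0.25, adjusted p = 6.53e-05, and adjusted p = 0.106 with an estimated correlation), with AATBC at 1.36 ± 0.14. Intergenic noncoding genes had 198 of 1498 higher and 16 lower (median 0.26, adjusted p = 4.79e-05, and adjusted p = 0.0943 with an estimated correlation). Small nucleolar RNA genes rose with indisulam in 40 of 114 cases and fell in 3 (median 0.53, adjusted p = 0.000479, and adjusted p = 0.0238 with an estimated correlation), with SNORD94 at 2.15 ± 0.20. Polyadenylated RNA was sequenced, so these counts may come from host transcripts, and their median was 0.185 with the GC and length trends removed.

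The interferon list was not called in any comparison, with 5 of 23 members higher and 5 lower in indisulam and 8 higher and 9 lower in the combination. The first members by p were DDX58 (2.75), ISG20 (1.25), IFI35 (2.37) and STAT2 (-0.83) in indisulam, and ISG20 (2.58), IFI35 (4.92) and DDX58 (2.46) in the combination. Library GC content varied within groups: the correlation of a library's deviation with GC content was -0.783 in DMSO replicate 3. Combination replicates 1 and 3 were at -0.648 and -0.753, and replicates 2 and 4 at 0.618 and 0.782. In the same order of pairs, CDKN1A was at 945 and 1052 against 1528 and 1539 CPM. HSPA6 was at 34.1 and 38.1 against 63.8 and 81.7 CPM, while MDM2 was at 504 and 510 against 483 and 462. A link between the 2 was not tested.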
